A study of Chlorocebus aethiops vervet with 14 samples.

How the data were processed

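RNA from the lateral geniculate nucleus of normal adult vervet monkeys was measured on 14 arrays, 12 of the Rhesus Macaque Genome Array and 2 of the human HG-U133 Plus 2.0 array. Tissue had been taken by laser capture under a cresyl violet stain, and the RNA went through double amplification with the Affymetrix system before hybridization, per the labels' protocols. The rhesus arrays fall into 4 groups of 3 by title: neuronal cell bodies of the magnocellular layers (M neurons), neuronal cell bodies of the parvocellular layers (P neurons), whole magnocellular layers (M layers) and whole parvocellular layers (P layers). Each group comes from 3 individual animals, and whether the same animals supplied all 4 groups is not given in the sources used here.

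The deposited intensity of each probe set is a linear signal computed by MAS5 before the values were deposited, per the submitters' processing notes, whose version is not given in the sources used here. MAS5 combines the probe pairs of a set into a background-adjusted signal, and low signals carry large relative errors. Detection calls were not used here. MAS5 commonly scales each array to one trimmed mean, but the 2% trimmed mean of the deposited signal ran from 60.1 to 90.7 over the rhesus arrays and from 33.4 to 41.0 over the human arrays. No common scaling target therefore holds for these values, and the scale of an array is not known. The vervet RNA was hybridized to probes designed on rhesus or human sequence, so a probe that mismatches the vervet transcript reads low in every group. Levels of different probe sets are not comparable for that reason, and only differences of 1 probe set between groups were tested.

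The rhesus array held 52865 probe sets, of which 99 were control probe sets. Of the other 52766, 24956 carried 1 gene symbol in the platform annotation, 361 carried several and 27449 carried none. Genes are named only from probe sets with 1 symbol, and the annotation can be old. No genome was used here, so no coordinates are given. The human array held 54675 probe sets.

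The main test was limma 3.58.1 in R 4.3.3 on log2(signal + 16), with the deposited signal otherwise unchanged. A difference on this scale understates the change of dim probe sets. Probe sets entered the test when their mean over the rhesus arrays reached the median of all probe sets outside the controls, which kept 26383 probe sets and 10029 named genes. The lowest mean signal kept was 12.01. One linear model with 4 group means took in all 12 rhesus arrays, with 8 residual degrees of freedom and a moderated variance that followed the intensity (11.66 prior degrees of freedom). Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over probe sets, and a probe set is called at an adjusted p under 0.05. Errors are the model's standard errors (SE) for differences and standard deviations (SD) for group means of the signal, with n = 3 in each group. The number of arrays limits the precision.

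The comparisons were M against P in neurons, in layers and over both captures, neurons against layers in M, in P and over both, and the interaction of layer type with capture. They share arrays and an estimate of the spread. Gene lists numbered 25 and covered glial, vascular and neuronal markers, channels, receptors, axons, release, metabolism, ribosome, proteasome, stress and guidance. The test of a list was limma's camera with a preset correlation of 0.01 on the brightest probe set of each gene, adjusted over the 25 lists. Camera was run again with the correlation estimated from the residuals, and no list call of any comparison held with it. The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined.

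Genes are named from M against P in neurons and in layers, and from neurons against layers, on the brightest probe set of each gene. Symbols that start with LOC were left out. The named genes are up to 10 higher and up to 10 lower called genes with the largest log2 difference. Their arrays in one group all lay above those of the other. Added to these are the members of each list with the smallest p, the 5 smallest p of the interaction and a fixed panel of marker genes. Of that panel NEFH, PVALB, FOXP2, GAD1, GFAP and MBP were tested, CAMK2A and SLC17A7 fell below the signal filter, and NEFM, NEFL, CALB1, CALB2 and SLC17A6 were not analysed here.

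The titles number the samples 1 to 3 within each group. Deviations from the group means of arrays with the same number correlated across probe sets at 0.101 to 0.262 in every comparison of groups, and 12 of 12 arrays correlated best on average with their own number. Pairing therefore comes from the data and not from a statement in the labels, and a model with the number as a block is given beside a result where it moves it. For the interaction, which takes in all pairs, the lowest such correlation was 0.045. Instrument records with the arrays put them on 3 fluidics stations. Station 3 ran the M neurons and 1 P neuron array, station 4 ran 2 P neuron and 2 M layer arrays, and station 5 ran 1 M layer array and the P layers, so that station overlaps largely with group. Results are given with station as a block and within stations.

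The alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, no filter, a stricter signal filter, no intensity trend, array weights, only the groups compared, the replicate and station blocks, and leaving out each array. Controls for 5' and 3' ends were read from the dap spike, a bacterial RNA added before amplification, and from the array's GAPDH control. Differences in control measures between captures used exact permutation tests, two-sided, over 5 measures. These treat the 12 rhesus arrays as exchangeable, though each group holds 3 animals and arrays with the same number correlated. Differences between M and P were permuted within captures, and by exact sign flips of the pairs with the same number, both chosen after the values were seen. The 3' GAPDH control lay at or near the highest signal of an array, so its ratio reads the 5' signal.

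The method was tested on simulated data with changes added to 50 probe sets per size among 26383. Noise was drawn independently for each probe set and array, with no numbered pairs, shift between arrays or station. The shares of false calls therefore need not hold for the real comparisons. For M against P in neurons it recovered 6% of changes of 0.5 on the log2 scale, 48% of changes of 1, 96% of changes of 2 and 100% of changes of 3, and 6.72% of its calls were false. For M against P in layers the shares were 4%, 52%, 94% and 98%, with 2.36% false calls. For neurons against layers they were 12%, 90%, 98% and 100%, with 5.06% false calls. Figures were drawn with matplotlib 3.10.9.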

Results

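The lateral geniculate nucleus is the thalamic relay between retina and visual cortex. Its magnocellular layers hold large relay cells and its parvocellular layers smaller ones. The series asked how gene expression differs between the M and P layers, once in captured neuronal cell bodies and once in captures of whole layers with neuropil and glia. Correlations of log2 signal across probe sets ran from 0.969 to 0.983 between arrays of one group and from 0.943 to 0.977 between arrays of different groups, across probe sets that are not independent replicates. The median signal per array lay between 11.9 and 14.8 on the rhesus arrays. Values are MAS5 signals on a linear scale, differences are on the log2(signal + 16) scale, and p-values come from limma unless another test is named.

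Between M and P neurons a small set of genes was called, most with large differences. Smaller differences could be missed, since simulated changes of 0.5 were recovered in 6% of cases and changes of 1 in 48%. SLC12A1, a sodium-potassium-chloride cotransporter best known from kidney, rose in M neurons by 3.01 ± 0.32 (SE) on the log2 scale, an 8.06-fold difference (adjusted p = 4.95e-05), from a signal of 66.6 ± 35.9 (SD, n = 3) in P neurons to 618 ± 161. ITGA8, an integrin alpha subunit, rose by 2.25 ± 0.25 (adjusted p = 8.14e-05), and ITPR1, an inositol trisphosphate receptor that releases calcium from internal stores, rose by 1.48 ± 0.25 (adjusted p = 0.00881). In the other direction BHLHE22, a basic helix-loop-helix transcription factor, was 7.99-fold lower in M neurons (SE 0.37 on the log2 scale, adjusted p = 0.00033), with 770 ± 399 in P neurons and 81.7 ± 41.8 in M neurons. PCDH20, a protocadherin adhesion molecule, changed by -2.92 ± 0.25 (adjusted p = 2.45e-06), from 186 ± 86.6 in P neurons to 9.18 ± 1.33 in M neurons, a signal near the bottom of the range. The probe sets were MmugDNA.28461.1.S1_at for SLC12A1, MmugDNA.12745.1.S1_at for ITGA8, MmugDNA.18191.1.S1_at for ITPR1, MmuSTS.1381.1.S1_at for BHLHE22 and MmuSTS.2010.1.S1_at for PCDH20, and ITPR1 had 4 tested probe sets, of which 1 was called.

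**Figure D1:**
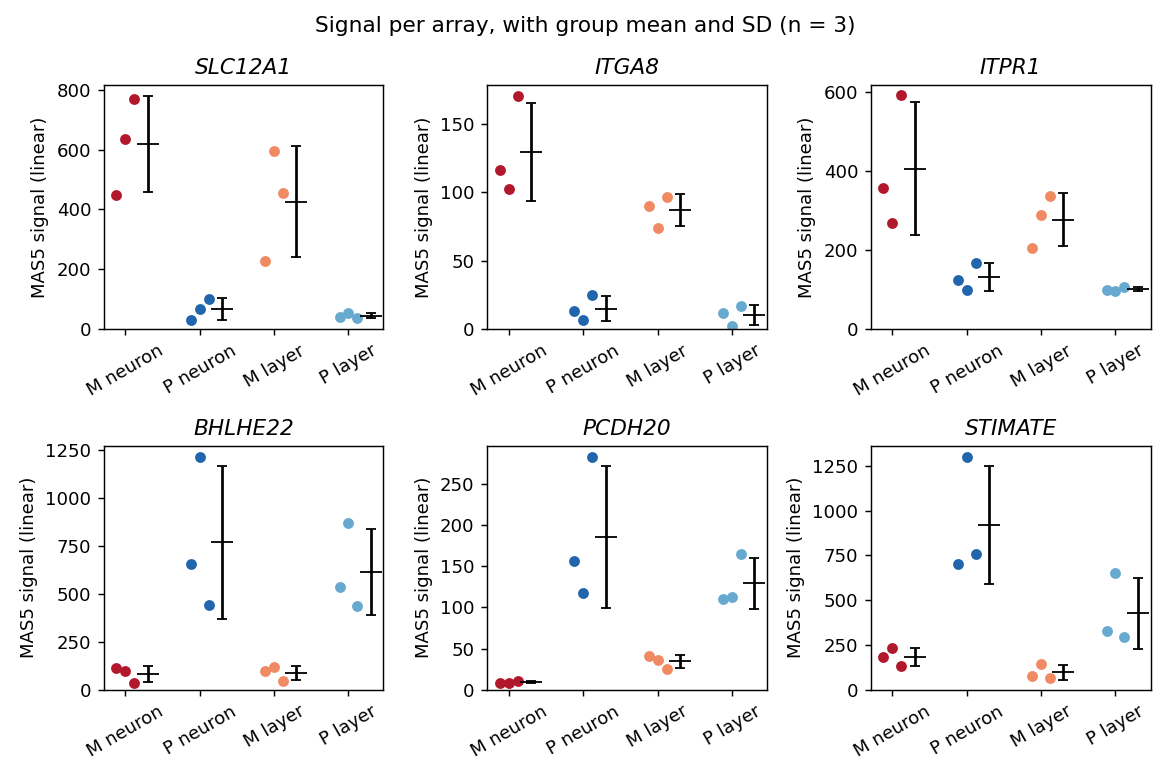
MAS5 signal per array (linear axis from 0, points) in the 4 groups for SLC12A1, ITGA8, ITPR1, BHLHE22, PCDH20 and STIMATE, with the group mean and SD (bars, n = 3). All 3 M arrays lie above all 3 P arrays of the same capture for SLC12A1, ITGA8 and ITPR1, and below them for the other genes.

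Other genes higher in M neurons were SPON2, an extracellular matrix protein (2.24), KCNJ6, a G protein-gated inward rectifier potassium channel subunit (1.55), the transcription factor EBF1 (1.49), the metalloprotease TLL1 (1.44), PEBP4 (1.23), CFAP184 (1.15) and the cell junction protein CGNL1 (1.12). Genes lower in M neurons included CARTPT, the precursor of the CART neuropeptides (-2.25), STIMATE, an endoplasmic reticulum protein of calcium entry (-2.22), TENT5A (-2.09), FABP4, a fatty acid binding protein (-2.05), REC8, a cohesin subunit (-1.81), DAPK1, a death-associated protein kinase (-1.71), the LIM domain protein CSRP2 (-1.40) and the cell cycle inhibitor CDKN2A (-1.30). Adjusted p-values of these genes lay between 0.000654 and 0.0293. The M neuron signals of FABP4 (7.43 ± 6.44), CDKN2A (9.74 ± 4.35) and TENT5A (10.7 ± 7.85) lay under the medians of the arrays, so the sizes of their differences rest on the pseudocount. With a pseudocount of 1 or 64 they were -3.63 or -1.02 for FABP4, -2.24 or -0.59 for CDKN2A and -3.38 or -1.11 for TENT5A. Sizes of other genes moved too, to 3.18 or 1.29 for ITGA8, 2.78 or 1.47 for SPON2 and -2.35 or -1.09 for REC8. CFAP184 went to 1.58 or 0.64 and PEBP4 to 1.6 or 0.73, while CSRP2 stayed at -1.44 or -1.28. In all, 77 of 26383 probe sets were called, 26 higher and 51 lower in M, from 39 named genes, and 1966 had an unadjusted p under 0.05. Called probe sets outside the naming rule included those of HINT1, higher in M at 2.07 and 2.16 in neurons and at 2.12 and 1.95 in layers. MGARP (-1.73) and ST8SIA4 (-1.48), lower in M neurons, were outside it too. So was LIN7A, higher in M layers (1.15 to 1.42) and called in neurons as well on probe sets at 1.07 and 0.985. For HINT1, MGARP, ST8SIA4 and, in layers, LIN7A, the called probe set was not the gene's brightest or left arrays overlapping. These differences need not stand for the gene.

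Of the panel, no gene was called in neurons. NEFH, the heavy neurofilament subunit of large axons, stood at 0.31 ± 0.10 (adjusted p = 0.348), GFAP at 0.58 ± 0.22 (0.467), GAD1 at 0.32 ± 0.29 (0.883), FOXP2 at 0.16 ± 0.28 (0.96), PVALB at 0.03 ± 0.30 (0.995) and MBP at -0.09 ± 0.13 (0.944). The oligodendrocyte and myelin list was lower in M neurons, with a median of -0.36 over 11 genes (camera adjusted p = 0.000882). Its adjusted p = 0.998 with an estimated correlation. None of its members was called over all genes (0 by limma), 1 fell when adjusted over the list alone, and UGT8, which makes myelin galactolipids, stood at -0.55 (adjusted p = 0.268), ENPP2 at -0.49 (0.498) and MAL at -0.43 (0.626). None of the other 24 lists passed, with camera adjusted p from 0.198 to 0.995. Potassium channel genes KCNAB1 (0.56) and KCNA2 (0.34) were not called either, nor was HRH1, a histamine receptor (-1.20, adjusted p = 0.151, and 0.00281 with the replicate number as a block), nor AGT (-1.15, adjusted p = 0.237, and 0.00281 with that block).

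With the replicate number as a block 188 probe sets were called and with fluidics station as a block 10, and within station 3, where the P arm was 1 array, 35 were called. With station as a block only SLC12A1, ITGA8, PCDH20 and BHLHE22 of the 20 genes named by the rule kept their call (adjusted p of the others from 0.125 to 0.645). The other 16 kept their direction at 0.6 to 1.08 times the difference without the block (median 0.97). The SEs of the 20 became 1.13 to 1.48 times as wide, so most of these calls ended by lower precision. SPON2 went from 2.24 ± 0.45 to 2.43 ± 0.63, KCNJ6 from 1.55 ± 0.28 to 1.63 ± 0.37, ITPR1 from 1.48 ± 0.25 to 1.51 ± 0.36 and REC8 from -1.81 ± 0.24 to -1.75 ± 0.35. The difference shrank for TENT5A, from -2.09 ± 0.32 to -1.26 ± 0.36, FABP4 from -2.05 ± 0.31 to -1.35 ± 0.39 and CARTPT from -2.25 ± 0.44 to -1.69 ± 0.58. Quantile normalization ended the calls of SPON2 (adjusted p = 0.0768) and CARTPT (0.0518), and testing all probe sets with no signal filter ended those of SPON2, EBF1, PEBP4, CARTPT and CSRP2 (adjusted p from 0.0561 to 0.126). A pseudocount of 1 ended those of CARTPT (0.0577) and TENT5A (0.116). The call of SPON2 ended with a pseudocount of 64 (0.0525) and with no intensity trend (0.0555), and that of PEBP4 with only the groups compared (0.0714). Leaving out M_neuron 3 and M_layer 1 together ended the calls of EBF1 (0.0951), PEBP4 (0.118), CFAP184 (0.0573) and CARTPT (0.0573). Without P_neuron 2 the count fell to 28 and the calls of SPON2, KCNJ6, EBF1, ITPR1, PEBP4, CFAP184, CGNL1, CARTPT, DAPK1, CSRP2 and CDKN2A ended (adjusted p from 0.0673 to 0.153). Without M_neuron 2 it was 43 and SPON2 had an adjusted p of 0.158. Other single arrays ended some of the same calls, and the list call of oligodendrocyte genes ended without M_neuron 3 (adjusted p = 0.0925).

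In whole layers the same direction held for the leading genes. SLC12A1 rose in M layers by 2.78 ± 0.32 (6.86-fold, adjusted p = 0.000269), with a signal of 425 ± 186 (SD, n = 3) against 44.5 ± 9.16 in P layers. ITGA8 rose by 2.01 ± 0.25, TLL1 by 1.44 ± 0.24 and ITPR1 by 1.30 ± 0.25. BHLHE22 changed by -2.62 ± 0.37 (adjusted p = 0.00385), from 614 ± 226 in P layers to 87.6 ± 38.1 in M layers, and FABP4 (-1.98), STIMATE (-1.95), PCDH20 (-1.51) and REC8 (-1.29) were lower as well. FABP4 in M layers (5.50 ± 4.04) and ITGA8 in P layers (10.3 ± 7.32) lay under the medians of the arrays, so the sizes of their differences rest on the pseudocount. Further called genes were PBXIP1 (1.03), CGNL1 (1.02) and CHN1, a GTPase-activating protein for Rac (0.68), higher in M, and CNTNAP4, a contactin-associated cell adhesion protein (-1.05), lower in M. The called probe sets numbered 42, with 26 higher and 16 lower in M (61.9% higher), from 18 named genes, and 1537 had an unadjusted p under 0.05. Quantile normalization called 71, of which 50.7% were higher.

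GFAP, the intermediate filament of astrocytes, stood at 1.03 ± 0.22 in M layers against P layers, with 1375 ± 283 against 658 ± 91.6 (adjusted p = 0.0656, and 0.00166 with the replicate number as a block). GAD1 stood at 0.96 ± 0.29 (adjusted p = 0.435), NEFH at 0.37 ± 0.10 (0.317), FOXP2 at 0.18 ± 0.28 (0.994), MBP at -0.10 ± 0.13 (0.994) and PVALB at -0.14 ± 0.30 (1). Lists higher in M layers were those of astrocytes, the proteasome and oxidative phosphorylation. The astrocyte list had a median of 0.29 over 12 genes (camera adjusted p = 0.0316, adjusted p = 0.923 with an estimated correlation), with 0 members called over all genes and 2 higher when adjusted over the list alone. FGFR3 stood at 0.61 (adjusted p = 0.21), while AGT lay the other way (-0.73). The proteasome list had a median of 0.23 over 24 genes (adjusted p = 0.00192), led by PSMB7 (0.58) and PSMD9 (0.50), and the oxidative phosphorylation list a median of 0.16 over 52 genes (adjusted p = 0.00456), led by ATP5PF (0.48), with 0 members of either called over all genes or adjusted over the list alone. For both of these lists adjusted p = 0.923 with an estimated correlation, and the other lists had camera adjusted p from 0.376 to 0.998.

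With the replicate number as a block 91 probe sets were called in layers and with station as a block 14, and within station 5, where the M arm was 1 array, 34 were called. Station as a block ended the calls of FABP4 (adjusted p = 0.273), PCDH20 (0.118), REC8 (0.327), ITPR1 (0.327), PBXIP1 (0.484), CGNL1 (0.357), CHN1 (0.306) and CNTNAP4 (0.0751). These 8 kept their direction at 0.9 to 1.36 times the difference (median 1.2). The SEs of the 13 genes named here became 1.25 to 1.52 times as wide, so the calls ended by lower precision. ITPR1 went from 1.30 ± 0.25 to 1.59 ± 0.36, PCDH20 from -1.51 ± 0.25 to -1.78 ± 0.36, CNTNAP4 from -1.05 ± 0.20 to -1.42 ± 0.27 and FABP4 from -1.98 ± 0.31 to -1.78 ± 0.39. With no signal filter the same 8 calls ended (adjusted p from 0.052 to 0.211). The count fell to 10 without P_layer 3, which ended the calls of TLL1, ITPR1, PBXIP1, CGNL1, CHN1, PCDH20, REC8 and CNTNAP4 (adjusted p from 0.0628 to 0.214), to 23 without P_layer 2, when FABP4 had an adjusted p of 0.0607, and to 24 without P_layer 1. The astrocyte call ended without M_layer 1 (adjusted p = 0.458), P_layer 2 (0.0642) or P_layer 3 (0.0949), after quantile normalization (0.089), with station as a block (0.949), with the mean over probe sets (0.227) and without M_neuron 3 and M_layer 1 together (0.457).

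Over both captures 222 probe sets were called between M and P, 114 higher and 108 lower in M, from 127 named genes, and 2609 had an unadjusted p under 0.05. NEFH rose in M by 0.34 ± 0.07 (adjusted p = 0.023), from 7846 ± 902 (SD, n = 3) to 9707 ± 331 in neurons and from 6773 ± 319 to 8742 ± 493 in layers. These signals lay not far below the highest signal of an array (10369 to 12183). The size of the NEFH difference may therefore be understated in each comparison. GFAP rose by 0.81 ± 0.15 (adjusted p = 0.0101) on its brighter probe set, and its second probe set stood at -0.04 (adjusted p = 0.979). The probe sets of FOXP2 differed too, but there the dimmer one was called. FOXP2 stood at 0.17 ± 0.20 (adjusted p = 0.862) on the brighter probe set and at -1.27 ± 0.23 (adjusted p = 0.00721) on the dimmer one. TCF7L2, a thalamic transcription factor (-0.36, adjusted p = 0.0444), HRH1 (-0.95, adjusted p = 0.044) and the ephrin receptor EPHA5 (-0.79, adjusted p = 0.0475) were lower in M. GAD1 (0.64, adjusted p = 0.197), MBP (-0.10) and PVALB (-0.05) were not called, nor were KCNA2 (0.33, adjusted p = 0.0624) and KCNAB1 (0.50, adjusted p = 0.0855, and 0.043 with the replicate number as a block).

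The oligodendrocyte list was lower in M over both captures (median -0.24, 0 of 11 members called), and oxidative phosphorylation (median 0.12, 0 of 52) and proteasome (median 0.17, 0 of 24) were higher, with camera adjusted p = 0.00476 for each, adjusted p = 0.995 with an estimated correlation, and 0 members of each when adjusted over the list alone. UGT8 stood at -0.34 and ENPP2 at -0.33 in the first, UQCRQ at 0.25 in the second and PSMB7 at 0.35 in the third. The list calls ended without M_neuron 3 (adjusted p = 0.0526 for each), that of oligodendrocyte genes also without M_layer 3 (0.0567). Of the lists 6 passed without P_neuron 1, and 5 passed with the replicate number as a block, with immediate early genes (adjusted p = 0.0271) and receptors for monoamines, acetylcholine and peptides (0.0386) added. That block called 473 probe sets and station as a block 51, which ended the calls of GFAP (from 0.81 ± 0.15 to 0.63 ± 0.22, adjusted p = 0.394), NEFH (from 0.34 ± 0.07 to 0.38 ± 0.11, 0.256), HRH1 (from -0.95 ± 0.22 to -0.56 ± 0.27, 0.583), EPHA5 (from -0.79 ± 0.18 to -0.78 ± 0.26, 0.374) and TCF7L2 (from -0.36 ± 0.08 to -0.30 ± 0.13, 0.519). The SEs widened for all 5, and the difference shrank most for HRH1. With no signal filter and with no intensity trend the calls of NEFH (adjusted p = 0.224 and 0.298), TCF7L2 (0.214 and 0.283), EPHA5 (0.13 and 0.0986) and HRH1 (0.145 and 0.0653) ended. A pseudocount of 1 ended those of TCF7L2 (0.0568), EPHA5 (0.0717) and HRH1 (0.101). The size of the HRH1 difference rests on the pseudocount, at -1.64 with 1 and -0.45 with 64. Without P_neuron 2 the count was 134 and the calls of NEFH (adjusted p = 0.0951), HRH1 (0.134), EPHA5 (0.0994) and TCF7L2 (0.126) ended, as they did without several other arrays. Without P_layer 1 the count was 144.

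Of the probe sets called in either capture, 17 were higher in M in both and 16 lower in both, and none was called in opposite directions (0 by limma). Independent lists of these lengths would share 0.0256 and 0.0309, but these lists are not independent. Both comparisons use one estimate of the spread, arrays with the same number correlated, and whole layers hold neurons too. Neurons and layers were separate arrays, and 74 of the 77 neuron calls and 42 of the 42 layer calls had the same sign in the other capture. The differences correlated across all tested probe sets at r = 0.348 (Spearman 0.251). For a pair of groups of 3, chance puts all arrays of one group above the other in 10% of probe sets.

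**Figure D2:**
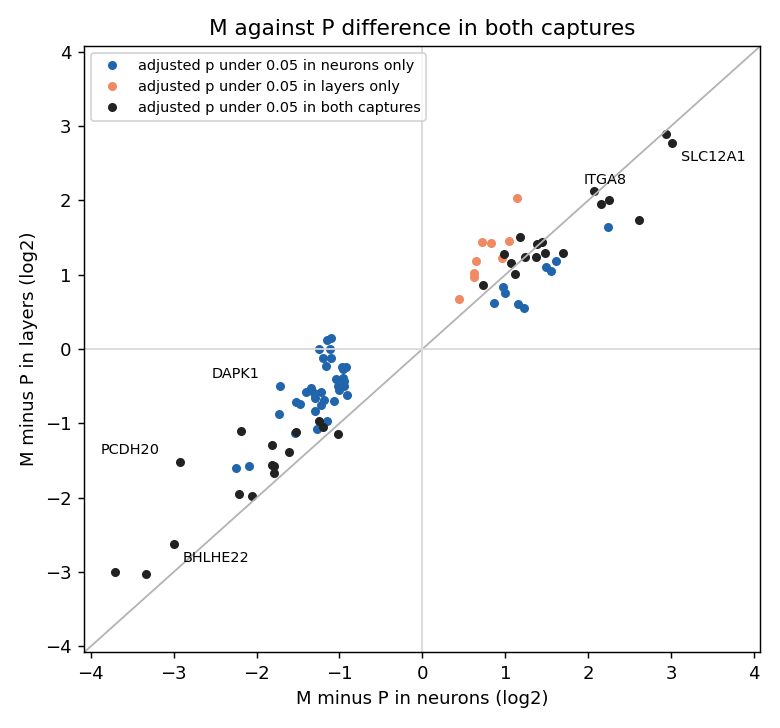
Log2 difference of M minus P in neurons (horizontal) against that in layers (vertical) for the 86 probe sets called in either capture, coloured by where they were called, with the line of equal differences. The 33 called in both lie in the upper right or lower left quadrant, and 44 were called in neurons alone and 9 in layers alone.

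No probe set was called for the interaction of layer type with capture (0 by limma, 743 at an unadjusted p under 0.05). The smallest p-values belonged to SMARCD1 (-1.99), DIPK2A (-1.27), SMIM5 (-1.25), PCDH20 (-1.40) and SLC16A8 (1.38), each with an adjusted p of 1. Of the 23 genes named from the M and P comparisons, all 23 had the same direction in both captures. Over these genes alone the interaction of PCDH20 was -1.40 ± 0.35 (adjusted p = 0.0181) and DAPK1 had an adjusted p of 0.0842, but most of them were chosen for a large difference in neurons, which makes these p-values too small.

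Captured cell bodies differed from whole layers in a large share of probe sets. The tested probe sets as a whole stood 0.13 higher in neurons (median 0.132, which quantile normalization removed by a shift of 0.127), so differences of genes are given relative to that median. Adjusted p-values, calls and counts of genes that rose or fell test the difference before the median was taken off, and camera compares a list with the other genes. Among the higher genes TPI1, a glycolytic enzyme, was 1.41 ± 0.14 above the median (2.66-fold, adjusted p = 6.46e-07), NDUFV1, a subunit of respiratory complex I, 1.35 ± 0.13, and the aminotransferase GOT1 1.29 ± 0.14. Among the lower genes SELENOP, a selenium transport protein, stood at -1.88 ± 0.16 (adjusted p = 6.53e-07), from 2497 in M layers and 3025 in P layers to 579 and 1110 in the neurons, and the fibroblast growth factor receptors FGFR2 and FGFR3 at -1.54 ± 0.15 and -1.42 ± 0.11 (n = 6 in each capture).

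Other higher genes were GAPDH (1.94), PRICKLE4 (1.51), PHB1, a mitochondrial prohibitin (1.41), AHNAK2 (1.41), the tubulin TUBB (1.31), NDRG4 (1.30) and the kinetochore gene MIS12 (1.30). The array's own GAPDH control was higher at its 5' end in neurons, from 352 ± 19.5 in M layers and 317 ± 13.0 in P layers to 1438 ± 446 and 1256 ± 247 in the neurons (SD, n = 3), while its 3' end, at 10180 to 11300 in all groups, lay at or near the highest signal of an array (10369 to 12183) and could hardly show a rise. Other lower genes were SPTBN1, a spectrin (-1.63), EVI2A (-1.44), SLC45A2 (-1.41), the tight junction protein TJP1 (-1.39), RFTN2 (-1.38), the transcription factor NFIB (-1.38) and ANLN (-1.36). SPTBN1 and TPI1 each had another probe set with the opposite sign. In all, 6354 of 26383 probe sets were called, 5139 higher and 1215 lower in neurons (80.9% higher), from 3608 named genes, and 9292 had an unadjusted p under 0.05. Quantile normalization called 5482, of which 51.9% were higher, and 2838 of the 5139 and 1210 of the 1215 kept their call.

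Energy lists were higher in neurons. Of 52 oxidative phosphorylation genes 36 rose and 1 fell (40 and 2 adjusted over the list alone), with a median 0.40 above that of all genes (camera adjusted p = 2.23e-10, adjusted p = 0.343 with an estimated correlation), among them NDUFA2 (1.16) and NDUFS3 (1.05). Of 12 glycolysis genes 10 rose, also adjusted over the list alone (adjusted p = 6.63e-06, adjusted p = 0.259 with an estimated correlation), with ALDOA at 0.77 and the hexokinase HK1 at 0.67. Of 24 proteasome genes 21 rose (22 adjusted over the list alone), with PSMB7 at 1.00 and PSMD2 at 0.89 (adjusted p = 3.19e-09, adjusted p = 0.259 with an estimated correlation). Of 19 voltage-gated potassium channel genes 9 rose (10 adjusted over the list alone), among them KCNA1 and KCNIP4 (0.91 each) and KCNA4 (0.78), with a median 0.27 above that of all genes (adjusted p = 0.0375, adjusted p = 0.603 with an estimated correlation). The potassium channel call ended without P_neuron 3 (adjusted p = 0.0535), P_layer 2 (0.0501) or M_neuron 3 and M_layer 1 together (0.0562), with a pseudocount of 1 (0.0503), with a stricter signal filter (0.194) and with the dap ratio as a covariate and the replicate number as a block (0.149). With that covariate and block the calls of oxidative phosphorylation, glycolysis and proteasome stayed.

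Lists of other cell types were lower in neurons. Of 12 astrocyte genes 7 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 3.6e-08, adjusted p = 0.155 with an estimated correlation), with the glutamate transporters SLC1A3 at -1.22 and SLC1A2 at -0.92 and the aldolase ALDOC, which the glycolysis list holds too, at 0.36. GFAP stood at -0.87 on its brighter probe set, while its dimmer one rose by 0.54 before the median was taken off (adjusted p = 0.0305). Of 11 oligodendrocyte genes 7 fell (8 adjusted over the list alone; camera adjusted p = 2.23e-10, adjusted p = 0.203 with an estimated correlation), with ASPA at -1.31, ENPP2 at -1.16 and UGT8 at -1.10, while MBP at -0.32 was not called (adjusted p = 0.155, and 0.0435 after quantile normalization). The oligodendrocyte precursor list (1 of 6 fell, 2 adjusted over the list alone, VCAN -1.20; adjusted p = 0.00153) and the microglia list (3 of 13 fell, also adjusted over the list alone, P2RY12 -0.96; adjusted p = 0.00153) were lower too. So was the endothelial and mural list (4 of 10 fell, also adjusted over the list alone, VWF -1.05 and the glucose transporter SLC2A1 -0.98; adjusted p = 0.000576). For these 3 lists adjusted p = 0.25 with an estimated correlation. The GABAergic interneuron list was lower (adjusted p = 0.00612, adjusted p = 0.259 with an estimated correlation, and 0.086 after quantile normalization) with 0 of 6 members called over all genes or adjusted over the list alone. NPY stood at -0.74 (adjusted p = 0.0623, and 0.00289 with the replicate number as a block), GAD2 at -0.54 (0.0713, and 0.0497 with that block) and GAD1 at -0.53 (0.173, and 0.0188 after quantile normalization). With the dap ratio as a covariate and the replicate number as a block the calls of the oligodendrocyte (adjusted p = 0.0739), precursor (0.0549), microglia (0.0739), endothelial (0.114) and GABAergic (0.0817) lists ended. The astrocyte call stayed. Station as a block ended the endothelial call (0.172), station with the replicate block those of the endothelial (0.108) and GABAergic (0.104) lists, and a stricter signal filter the microglia call (0.0582).

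**Figure D3:**
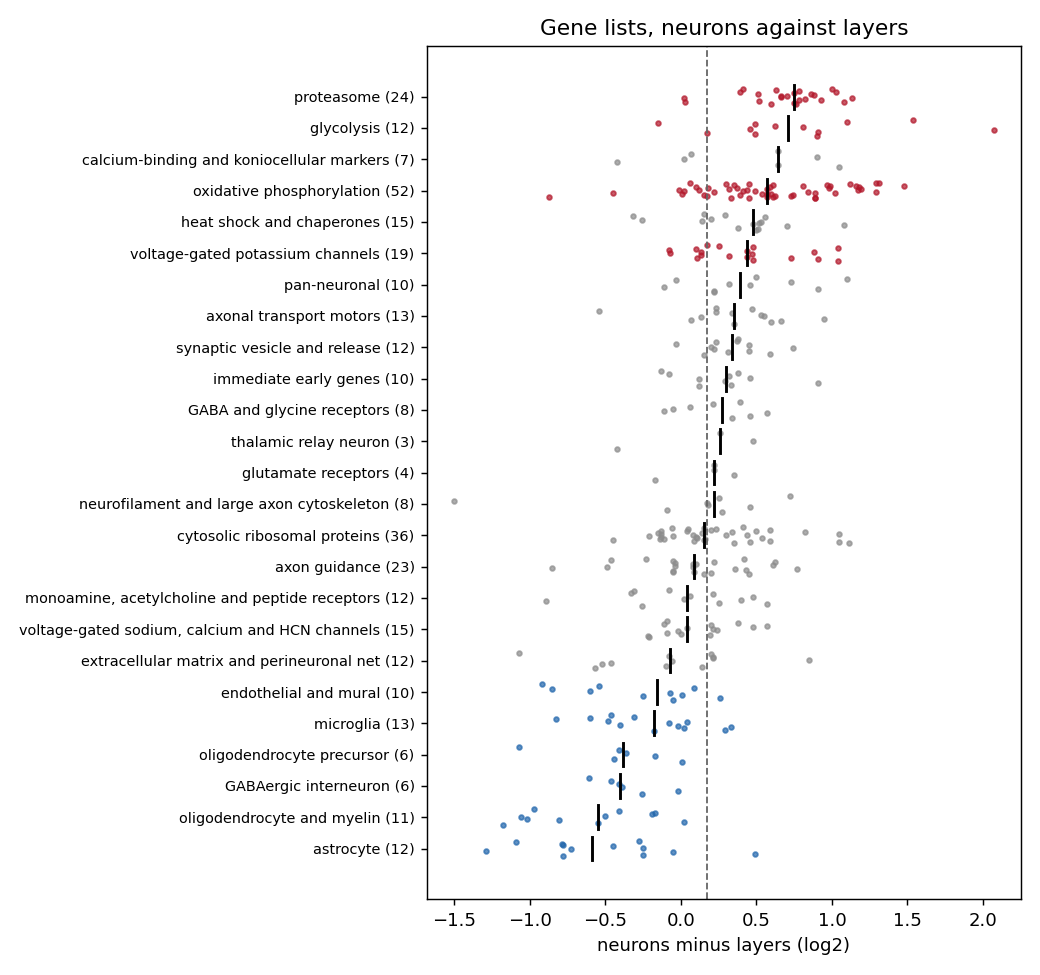
Log2 difference of neurons minus layers (horizontal, before the median was taken off) for each gene of the 25 lists, with the number of tested genes in brackets, the list's median as a black bar and the median of all genes, 0.172, as a dashed line. Lists in red were higher and lists in blue lower by camera with its preset correlation, and lists in grey did not pass.

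Neuronal markers rose in part. Of 10 pan-neuronal genes 4 rose, also adjusted over the list alone, THY1 at 0.97, the neuronal enolase ENO2 at 0.77, STMN3 at 0.60 and STMN2 at 0.19, but the list did not pass (camera adjusted p = 0.12, and 0.0433 with the replicate number as a block). In the list of calcium-binding and koniocellular markers 4 of 7 rose, also adjusted over the list alone, CAMK2B at 0.92, NCALD at 0.77, PVALB at 0.51 and CAMK4 at 0.50, with a list adjusted p of 0.244. FOXP2 stood at -0.55 (adjusted p = 0.141), and its dimmer probe set rose by 0.66 before the median was taken off (adjusted p = 0.0406). Of 3 relay neuron genes RORA and TCF7L2 were called before the median was taken off (list adjusted p = 0.972, with 2 higher and 1 lower adjusted over the list alone), and relative to it RORA stood at 0.35 ± 0.14 and TCF7L2 at 0.12 ± 0.08. NEFH stood at 0.05 ± 0.07 relative to the median and at 0.18 before it was taken off (adjusted p = 0.076, and 0.0443 after quantile normalization). The NEFH signal lay near the top of the range, so a larger difference could be hidden. After quantile normalization CAMK4, RORA, TCF7L2 and PVALB were no longer called (adjusted p from 0.086 to 0.182). The lists of neurofilament and large axon genes (0.972), sodium, calcium and HCN channels (0.57), glutamate receptors (0.992), GABA and glycine receptors (0.798), immediate early genes (0.739) and heat shock and chaperone genes (0.0969) had camera adjusted p over the threshold. In the neurofilament and glutamate receptor lists the median lay above that of all genes while camera ranked the list lower. Leaving out single arrays ended the calls of PVALB (highest adjusted p 0.0826, without P_layer 3), TCF7L2 (0.0954, without M_neuron 1), RORA (0.0523, without P_layer 3) and, among microglial genes, ITGAM (0.0897, without P_neuron 3).

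The controls for 5' and 3' ends moved with capture. The dap spike was added before amplification, so its ratio does not read the quality of the captured RNA. The dap spike kept a higher ratio of 5' to 3' signal in neuron arrays by 1.12 ± 0.09 on the log2 scale (2.17-fold, exact permutation p = 0.00216, the smallest that 6 against 6 arrays can give, 0.0054 after adjustment over 5 measures), with no overlap between captures. The same ratio of the GAPDH control was 1.98 ± 0.17 higher (exact permutation p = 0.00216, adjusted 0.0054), but with its 3' end at the top of the range it reads the 5' signal and is no separate measure of RNA length. The 3' signals of the spikes added before amplification were 0.97 ± 0.20 higher in neurons (exact permutation p = 0.00649, adjusted 0.0108), and hybridization controls differed by -0.06 ± 0.05 (exact permutation p = 0.286). Between M and P none of the 5 measures passed in exact permutations within captures (p from 0.065 to 0.945). The dap ratio was 0.17 ± 0.05 higher in M, in 5 of 6 pairs with the same number (exact sign-flip p = 0.0625, adjusted 0.312 over the 5 measures, where the smallest possible is 0.0312).

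**Figure D4:**
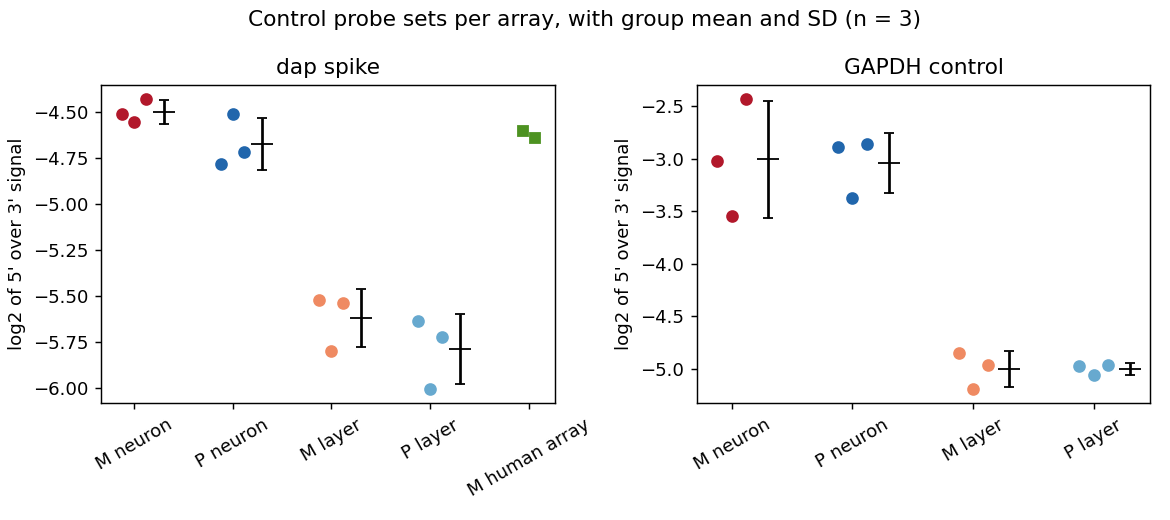
Log2 ratio of 5' to 3' signal per array (points) for the dap spike and the GAPDH control in the 4 rhesus groups, with the group mean and SD (bars, n = 3), and for the dap spike on the 2 human arrays (squares). All neuron arrays lie above all layer arrays in both panels, and the human arrays, at -4.60 and -4.64, lie in the range of the neuron arrays.

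With station as a block 616 probe sets were called between neurons and layers, and within station 4, which ran 2 P neuron and 2 M layer arrays, so that layer type was mixed in, 1252 were called. Of 72 called genes followed through the settings, 31 kept their call with that block and 41 lost it, 39 of these in the same direction. Among the 41 were PRICKLE4, TJP1, NFIB, NDUFA2, HK1 and KCNA4, the glial and vascular genes SLC1A2, ALDOC, GFAP, UGT8, VCAN, P2RY12, ITGAM and SLC2A1, and the neuronal genes ENO2, STMN3, STMN2, NCALD, CAMK4, RORA, TCF7L2 and PVALB. The median ratio of the difference with to that without the block was 1 for the 41. The SEs of the 72 became 1.5 to 2.52 times as wide, so that most lost precision. Before the median was taken off UGT8 went from -0.97 ± 0.12 to -1.02 ± 0.29 (adjusted p = 0.0613) and ENO2 from 0.91 ± 0.13 to 1.09 ± 0.33 (0.0757). SLC1A2 went from -0.79 ± 0.14 to -0.54 ± 0.31 (0.351), SLC2A1 from -0.85 ± 0.13 to -0.37 ± 0.30 (0.529) and PVALB from 0.64 ± 0.21 to -0.60 ± 0.31 (0.292). With the dap ratio as a covariate and the replicate number as a block 1 was called.

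Within M, 2805 probe sets were called between neurons and layers (73.2% higher in neurons, 48.0% after quantile normalization; 6452 at an unadjusted p under 0.05), and within P, 2686 (86.2%, 51.5% after quantile normalization; 6518 unadjusted). Shared calls were 1329 higher and 276 lower, with 0 in opposite directions by limma, and independent lists would share 180 and 10.6. The differences correlated across probe sets at r = 0.703 (Spearman 0.645). M and P captures were separate arrays, but these lists are not independent. Both share the estimate of the spread, the shift between captures and the dap difference, so the overlap does not part capture from these. The count in M was 1868 without M_neuron 1, 1448 without M_neuron 3 and 1373 without M_layer 1, and that in P was 1677, 1702 and 1342 without P_neuron 1, 2 and 3, and 1128 and 1035 without P_layer 1 and 3. Station as a block left 33 and 115.

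Samples also run on the human array, M_human_array 1 and 2, carry conflicting labels. Their titles name the magnocellular layer and their source names the neuronal cell body. Their run notes carry the same short names, station and module as M_neuron 1 and 2. The labels conflict, so no capture type is assumed here. Over 7579 genes matched by symbol, the human signals correlated across genes with the M layer arrays of the same number at r = 0.632 and 0.635 (Spearman 0.609 and 0.614) and with the M neuron arrays at r = 0.662 and 0.664 (Spearman 0.649 and 0.651). The difference of sample 1 minus sample 2 on the human array correlated with the same difference of M neurons at r = 0.271, P neurons at 0.148, M layers at 0.12 and P layers at 0.076. Of 293 genes that differed by at least 1 on the log2 scale on the human array, 78.5% had the same sign in M neurons, 60.4% in P neurons, 47.4% in M layers and 49.8% in P layers. Genes are not independent replicates and these values carry no test.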

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

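Tests chosen only after the result was seen are those of scanner brightness, of glial content, of fluidics station and of the dap spike on the human arrays; the test of the dimmer probe sets, the other tests on the human arrays and the counts over drawn splits were set beforehand, while the count over all splits that part every numbered pair was added later.

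The 5' to 3' ratio of the dap spike was 1.12 higher in neuron than in layer arrays on the log2 scale, that of the GAPDH control 1.98 higher with its 3' end at the top of the range, so that its size reads the 5' signal only, and the 3' signal of the spikes 0.97 higher, in control probe sets that no comparison of genes uses. For PCDH20 the M against P difference in neurons minus that in layers was -1.4 on the log2 scale (limma, adjusted p = 1 over all probe sets). The adjusted p = 0.0181 over 23 named genes is too small, since most of them were chosen for a large difference in neurons. The M neuron signal of PCDH20 lay near the bottom of the range, so the size rests on the pseudocount. With a pseudocount of 1 or 64 the M against P difference was -4.11 or -1.72 in neurons and -1.87 or -0.96 in layers.

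Neurons stood above layers in 80.9% of called probe sets at the deposited scaling, but in 51.9% after quantile normalization, which removes a shift between arrays whatever its cause (48.0% within M). Brightness of hybridization or scan is argued against, since the hybridization controls lay lower in neurons, at -0.06, while the tested probe sets lay 0.13 higher. Fewer glial and vascular cells in the neuron captures may account for the lower side: 45 of 49 non-neuronal genes lay below the median of all genes, by a median of -0.58. Longer amplified RNA stays open. The test set beforehand, that dimmer probe sets gain more than the brightest of the same gene, came out against it at 0.029 (95% bootstrap interval 0.016 to 0.04, 3671 genes). But that bound was wrong, since a dimmer probe set need not lie nearer the 5' end. For the dap spike, whose ends are known, the ratio of 5' to 3' signal was 1.12 higher in neurons. Capture type and the dap ratio move together on these arrays, so capture and the length of amplified RNA cannot be told apart for the higher or the lower genes. With the dap ratio as a covariate and the replicate number as a block, 1 probe set was called between captures. Of the lower lists only that of astrocytes kept its call there. Higher energy metabolism in cell bodies stays untested.

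M and P neurons differed in 77 probe sets. Fluidics station stays open for most of them: 93.5% kept their direction among the layer arrays of station 5, but that rests on 1 M array, and with station as a block 10 probe sets were called, SLC12A1, ITGA8, PCDH20 and BHLHE22 among them, while 16 named genes lost their call at 0.6 to 1.08 times the difference, mostly since the SEs widened (SPON2 from 2.24 ± 0.45 to 2.43 ± 0.63, TENT5A from -2.09 ± 0.32 to -1.26 ± 0.36). A larger share of glia in the M captures is argued against for the 26 probe sets higher in M, with a median of 1.42, since the highest of 5 lists of other cell types, that of astrocytes, stood at 0.16 ± 0.16, and their median neuron minus layer difference was 0.4 ± 0.07 (relative to all probe sets 0.27 ± 0.07, and 0.11 ± 0.08 in the P captures), where astrocyte genes lay at -0.72. Glia in the P captures stay open for the 51 lower in M, with a median of -1.27: oligodendrocyte genes, at -0.36 ± 0.09, fell short of it but went the same way, and the median neuron minus layer difference was -0.06 ± 0.09 (24 of 51 above 0; relative to all probe sets -0.19 ± 0.09, and -0.5 ± 0.11 in the M captures, which choosing genes low in M neurons pulls down). A difference between M and P relay cells may underlie these calls and was not tested apart from these explanations.

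The human arrays carry both capture labels, and their run notes carry the short names, station and module of M_neuron 1 and 2. Layer captures are argued against by the dap spike, since the lower human ratio lay 0.88 above the highest rhesus layer array, where the SD of layer arrays was 0.18. Neuron captures stay open: the sample difference correlated 0.151 more with M neurons than with M layers, short of the 0.2 set beforehand. The position of 40 non-neuronal genes between rhesus neurons (0) and layers (1) averaged -0.04 with intervals of -0.97 to 0.84 and -0.6 to 0.74, which decides neither. A title that names the wrong capture is a candidate explanation.

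Other splits of the arrays into groups of the same sizes were counted, the real one included. Splits of 3 against 3 number 10 and cannot give a share under 0.05. Between M and P, 1 split gave as many calls in neurons (77, highest other 0) and 1 in layers (42, highest other 1). Between neurons and layers, 1 split gave as many in M (2805, highest other 2) and 1 in P (2686, highest other 0). For lists 9 gave as many as the 1 called in neurons (highest other 4) and 2 as many as the 3 in layers (highest other 4). Of 100 drawn splits for M against P over both captures, 2 gave as many as 222, the real one and one that called 982 by setting M_neuron 1, M_neuron 3, P_neuron 3, M_layer 2, M_layer 3 and P_layer 2 against the rest. The latter split parts 2 numbered pairs only and points to a structure of the samples. Each of the 31 others that part all 6 pairs as the real one does called 0 by limma, a share of 0.0312. That is the smallest share these splits can give, and they treat the 6 pairs as separate. The pairs carry only 3 numbers, so chance is not excluded. Of 100 for neurons against layers, 1 gave as many as 6354, with 3054 as the highest other. Of the 32 splits that part all 6 pairs, 1 gave as many, a share of 0.0312 with the same limit. The highest other, 1862, only exchanged M_neuron 2 with M_layer 2. For the interaction 85 gave as many as 743 at an unadjusted p under 0.05 (highest other 6134), and for lists 23 gave as many as 3 over M and P (highest other 6) and 15 as many as 10 over captures (highest other 15), so that chance is not excluded for the interaction or for the number of lists.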

How the results depend on the processing

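Alternatives chosen only after the data were seen are the dap covariate together with the replicate block, station together with the replicate block, and leaving out M_neuron 3 and M_layer 1, whose spike signals stood apart. Counts are given in the order M against P in neurons, in layers and over both captures. Quantile normalization called 130, 71 and 516, no filter 45, 15 and 136, the replicate block 188, 91 and 473, station as a block 10, 14 and 51, and station with the replicate block 45, 26 and 69. The dap covariate with the replicate block called 122 and 64 in neurons and layers, array weights 176 and 554 in layers and over both, and no intensity trend 27 in layers. Neurons against layers over both, in M and in P gave 616, 33 and 115 with station, 92, 19 and 18 with station and the replicate block, and 1, 1 and 1 with the dap covariate and the replicate block. Array weights gave 5499 in P, and in M only the groups compared gave 1668 and leaving out both arrays 824. The other counts stayed within 1.5 times, and the interaction had 0 calls by limma in every setting. The replicate block also added the pan-neuronal and extracellular matrix lists between captures (camera adjusted p = 0.0433 for each), and beyond the values in the report changed no other call of a named gene or list. For the comparisons over both captures and the interaction the setting with only the groups compared takes in the same 12 arrays and gives no other value. The cause of these changes was not tested, except that a station block removes most of the arrays that compare groups and the dap ratio parts the captures without overlap.

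Lists called between M and P in neurons were 2 with quantile normalization, with no filter, with a stricter signal filter and with the mean over probe sets, 3 with the dap covariate and the replicate block, and 0 with station and the replicate block or without both arrays; in layers 5 with the dap covariate and the replicate block; over both 5 with the replicate block and 0 with station and the replicate block. Between neurons and layers 6 were called with the dap covariate and the replicate block and 6 with a stricter signal filter. With an estimated correlation 0 were called in each (camera; 1, 3, 3 and 10 with the preset). The human arrays' mean correlation of 0.633 with M layers became 0.685 with no filter, 0.625 with the mean over probe sets and 0.663 with M neurons as the partner.

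Leaving out 1 array gave 28 (without P_neuron 2) to 86 in neurons, 10 (without P_layer 3) to 42 in layers, 134 (without P_neuron 2) to 243 over both, 4936 to 7383 between neurons and layers, 1373 (without M_layer 1) to 3600 in M, 1035 (without P_layer 3) to 3340 in P and 0 to 0 for the interaction. A group left with 2 arrays shares the spread of the others. Other arrays that moved a count over 1.5 times were M_neuron 2 (43 in neurons), P_layer 1 and 2 (24 and 23 in layers), P_layer 1 (144 over both), M_neuron 1 and 3 (1868 and 1448 in M), and P_neuron 1, 2 and 3 and P_layer 1 (1677, 1702, 1342 and 1128 in P). Lists ran from 0 (without M_neuron 3) to 3 (without M_neuron 2 or P_neuron 1) in neurons, 2 to 3 in layers, 0 (without M_neuron 3) to 6 (without P_neuron 1) over both and 9 to 11 between captures.

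Of 3887 alternative values for 154 named gene results, 3382 kept direction and side of the threshold. A call was lost in 434 and gained in 52, and 19 changed sign or came to 0 after rounding. FN1 between neurons and layers went to 0.29 with station and 0.23 with station and the replicate block, PCLO to -0.74 and MBP to 0.23 with the dap covariate and the replicate block together, and PVALB to -0.60 with station. Between M and P in neurons FOXP2 went to -0.14 with station, -0.03 with station and the replicate block and -0.14 without M_neuron 2, and MBP to 0.03 with array weights and 0.03 without M_neuron 2. PVALB went there to -0.24 with station, 0 with station and the replicate block, 0 with median centring, -0.02 with quantile normalization, -0.11 without M_neuron 1, -0.06 without M_neuron 2 and -0.24 without P_neuron 3. In layers FOXP2 went to -0.02 without P_layer 2 and PVALB to 0.34 without M_layer 3. Leaving out 1 array gave -0.14 to 0.53 for FOXP2, -0.24 to 0.27 for PVALB and -0.25 to 0.03 for MBP in neurons, and -0.02 to 0.31 for FOXP2 and -0.41 to 0.34 for PVALB in layers. The cause was not tested. Signal near the bottom of the range limits dim genes such as FOXP2.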

Other observations

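No test given here was chosen after its result was seen, and the lists were fixed before the data were examined. Between neurons and layers, gene differences are again on the log2 scale relative to the median of all tested probe sets. With station as a block NTNG1 kept its call (limma adjusted p = 0.0422). The calls of KIF1B (0.0781), KIF5B (0.113), SV2B (0.107), PCLO (0.055), HAPLN4 (0.0903) and ACAN (0.692) ended. So did those of RPL12 (0.152), RPL8 (0.0812), CHRM3 (0.321), CHRNA7 (0.0686), EPHA4 (0.0583) and EPHB1 (0.283). These genes kept their direction, with wider SEs.

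Axonal transport motors split in neurons against layers. KIF1B rose (0.82, adjusted p = 0.00171) and KIF5B fell (-0.67, adjusted p = 0.000277), and 7 of 13 genes rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.149). Of 12 synaptic vesicle genes 3 rose (5 adjusted over the list alone), among them SV2B (0.61) and PCLO (0.45), with a list adjusted p of 0.149.

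In the list of extracellular matrix and perineuronal net genes the link protein HAPLN4 rose (0.72), while ACAN (-0.70) and FN1 (-0.65) were among 3 of 12 that fell (1 up and 4 down adjusted over the list alone; camera adjusted p = 0.0571, and 0.0433 with the replicate number as a block). The call of FN1 ended without P_neuron 1 (adjusted p = 0.103) and without several other arrays. With station as a block its difference before the median was taken off turned from -0.52 ± 0.17 to 0.29 ± 0.35 (adjusted p = 0.694). Of 36 ribosomal protein genes 12 rose, also adjusted over the list alone, with RPL12 at 0.98 and RPL8 at 0.92 (camera adjusted p = 0.552), and the list's median minus that of all genes was -0.02 while camera ranked the list higher.

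Of 12 receptors for monoamines, acetylcholine and peptides the muscarinic CHRM3 rose (0.44) and the nicotinic CHRNA7 fell (-1.02), also adjusted over the list alone (camera adjusted p = 0.177). Of 23 axon guidance genes 4 rose and 3 fell, also adjusted over the list alone, with EPHA4 at 0.64, NTNG1 at 0.48 and EPHB1 at -0.98 (camera adjusted p = 0.57). None of these lists passed in the model as reported.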
